A study of Homo sapiens with 4 samples.

How the data were processed

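Naive H9 cells were profiled with the 10x Genomics 3' single-cell kit, version 3 chemistry, per the labels' protocols. The authors deposited raw UMI counts per gene and cell in 2 tables, one for each knockout clone with its WT control. Cell Ranger 3.0.2 and Seurat 3.1.5 are named in the submitters' processing notes, together with the human build GRCh38 (hg38) and the mouse build mm10, whose role is not given in the sources used here. The filters on cells and genes behind the deposited counts are not given in the sources used here. No mouse gene was listed in either table. The library of each cell was taken from the ending of its barcode name.

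The tables held 22257 genes (clone 18) and 21226 genes (clone 7), of which 20686 were in both and entered the tests. These held 99.996% and 99.998% of the UMIs of the tables. Gene positions came from GENCODE 29 on GRCh38: 17670 names matched by the same symbol, 485 by an older symbol and 34 matched several loci, while 4608 did not match. Genes with a position held 99.36% of the UMIs. The X-linked set left out XIST, TSIX and pseudoautosomal genes. Members of a list that were not in both tables or did not pass the count filter were left out of the planned tests. Of these, COL3A1 and LUM are given as counts further on. Cells needed at least 1000 detected genes and at most 20% mitochondrial UMIs, which removed 0 cells. Scrublet marked between 0.0282% and 0.313% of cells per library, under the 2% set as its expected rate, so its calls were not relied on. Whether it failed or doublets had been removed before deposit cannot be told from the sources used here. No doublets were removed, and cells above the 0.95 quantile of UMIs in each library were left out as an alternative instead.

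Cells are not replicates, so counts were summed per library. Sums were tested with the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3) after TMM normalization and filterByExpr, with clone as a block and Benjamini-Hochberg adjusted p under 0.05. The block rests on the labels, which give each WT library as the control of 1 clone. After the group means were removed, a knockout clone and its WT control deviated together (correlation 0.81 over 7220 genes). What the libraries of a pair share is not given in the sources used here, so the block may stand for a batch. The fit had 1 residual degree of freedom, moderated with a prior of 5.66, and a common dispersion of 0.0220. Standard errors of log2 changes were the change divided by the square root of the quasi-likelihood F statistic. Changes within 1 pair were log2 ratios of CPM with a prior count of 2 and carry no test. Sets were tested with camera and fry (limma 3.58.1), camera with a preset correlation of 0.01 and again with an estimated one. For each pair 10000 random lists matched on expression gave a percentile. Shares of UMIs were compared with an exact permutation test, 2 libraries against 2. In 5 simulated data sets of 16996 genes on the real libraries' means and sizes, of which 16683 to 16751 passed the count filter, the blocked fit called 482 of 500 genes changed by a log2 of 1 (96.4%) and 500 of 500 changed by 2. It also called 118 of 83980 unchanged genes, so false calls exceeded the nominal rate. Only genes with a mean of at least 10 CPM were changed there, by the same amount in both pairs, with the dispersions of the real fit. These rates do not carry over to rarer transcripts or to changes that differ between pairs. A simulated X-linked difference of 0.25 was called by camera with the preset correlation in 5 of 5 data sets, and one of 0 in 0 of 5. Genes were drawn independently of each other there. The simulation thus does not test camera where genes are correlated, as in the real X-linked set (estimated correlation 0.163).

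Clustering used 2000 variable genes, 30 components, 20 neighbours and Leiden resolution 0.5 (scanpy 1.11.5, leidenalg 0.10.2), each library centred. A cluster was named only from fixed markers. For the comparison of WT cells with and without XIST, cells were thinned to 15739 UMIs. For the alternative with equal depth, 2194 cells per library were thinned to 6984 UMIs.

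Groups, tests, alternatives, 21 gene lists and the rule for named genes were set before the data were examined. The rule named XIST first, then genes past the threshold, changed alike in both pairs and with a mean of at least 10 CPM (the 10 highest, the 10 lowest and 6 X-linked), and up to 4 members of each list with the smallest adjusted p. XIST was the only gene past the threshold, so the other genes named by the rule come from the lists, and any further gene is said to have been chosen after its values were seen. The value of 1 list member that the rule names is not reported here, though it stays in the counts. The alternatives tried were no replicate block, DESeq2 1.42.0 (size factors and Wald test), no count filter, a mean of at least 10 CPM, stricter cell filters, equal depth, doublet removal, other denominators, other Leiden resolutions and leaving out each library. The alternative of naive-like clusters alone was not run, because no cluster could be named naive-like. Naming needed markers that stood above the mean of the other clusters, so a type that most cells share could not be named. The naive marker DPPA5 stood at 188 CPM in the trophoblast-like cluster and at 1185.5 to 2382 CPM in the others.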

Results

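Single-cell RNA was measured in naive human embryonic stem cells of the established line H9, kept in 5iLAF medium at 5% oxygen. This medium holds cells in a state that resembles the preimplantation epiblast. Cells in which XIST had been knocked out were set beside wild-type (WT) cells. XIST is the long noncoding RNA that coats an X chromosome and silences its genes during X inactivation. There were 4 libraries, 2 of each genotype, and each knockout clone (clone 18 and clone 7) had a WT library of its own as control. The values were counts of unique molecular identifiers (UMIs) per gene and cell. The WT clone 18 library held 2825 cells and 136522545 UMIs (median 42825 per cell), and the XIST KO clone 18 library held 2533 cells and 94063616 UMIs (median 32491). The WT clone 7 library held 2233 cells and 66681057 UMIs (median 24272), and the XIST KO clone 7 library held 3541 cells and 56127067 UMIs (median 13044). In both pairs the knockout library was the shallower per cell. Nothing states that the libraries came from separate cultures beyond the clone, so p-values measure only the spread between these libraries, which may be technical. Intervals given for single libraries cover counting error only.

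XIST RNA was abundant in both WT libraries and nearly absent from both knockouts. In CPM, here UMIs scaled to equal library totals and for all other genes to library sizes adjusted by TMM, it reached 66.1 CPM (exact 95% Poisson interval 64.8 to 67.5) in WT clone 18 and 97.6 CPM (95.2 to 99.99) in WT clone 7. The XIST KO clone 18 library held 6 XIST UMIs (0.0638 CPM) and the XIST KO clone 7 library held 2 (0.0356 CPM). The WT level was 1036 times the knockout level in clone 18 (95% interval 476 to 2825) and 2739 times in clone 7 (758 to 22618). At least 1 XIST UMI was present in 46.7% of cells of WT clone 18 and 81.5% of WT clone 7, against 0.237% and 0.0565% of cells in their knockouts, which serve as the background of detection. The gene (ENSG00000229807.11) lies on chromosome X at 73820651 to 73852723 on the minus strand in GRCh38 and is annotated as a lincRNA. The labels do not say which part of it was deleted, so a 3' tag outside the deleted part would not have checked the genotype. In edgeR's quasi-likelihood fit with clone as a block, the log2 change (XIST KO minus WT) was -10.46 ± 0.25 (SE, 4 libraries; adjusted p = 4.81e-05). That fitted value depends on the prior count and is no bound.

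The title of the series asks whether XIST acts on X-linked and on autosomal genes. X-linked genes were higher in the knockout than in the WT library of both clones. The median X-linked gene stood 0.19 (log2; 1.14-fold) above the median autosomal gene in the clone 18 pair and 0.41 (1.33-fold) above it in the clone 7 pair. Of 552 X-linked genes, 438 (79.3%) were higher in the knockout of clone 18 and 450 (81.5%) in that of clone 7. In both pairs at once 378 X-linked genes (68.5%) were higher, against 25.1% of 14477 autosomal genes. Over both pairs the difference was 0.30 (1.23-fold). Camera with the preset correlation of 0.01 gave p = 2.75e-23, and this call was lost with an estimated correlation of 0.163, where p = 0.228. With no replicate block the difference was again 0.30, and p with an estimated correlation was 0.0443. Both pair medians lay above all 10000 random autosomal lists matched on expression, whose highest medians were 0.03 and 0.06, a description of these libraries only. Among genes with a mean of at least 10 CPM the difference was 0.20, more than 1.5 times smaller.

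Both arms of the X chromosome showed this difference, and within each pair no autosome had a median as high. Among genes of at least 10 CPM, the 106 genes of the short arm had a median log2 change of 0.14 in clone 18 and 0.26 in clone 7. The 139 genes of the long arm were at 0.17 and 0.33. The autosomes farthest from 0 were chromosome 5 (-0.05) and chromosome 12 (0.05) in clone 18, and chromosome 7 (-0.11) and chromosome 14 (0.12) in clone 7. Across X-linked genes of at least 10 CPM the changes of the pairs were correlated (245 genes, Pearson's r = 0.37), and across 6886 autosomal genes they were not positively so (r = -0.011, Spearman's rho = -0.090). These are correlations across genes, which are not independent replicates.

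**Figure D1:**
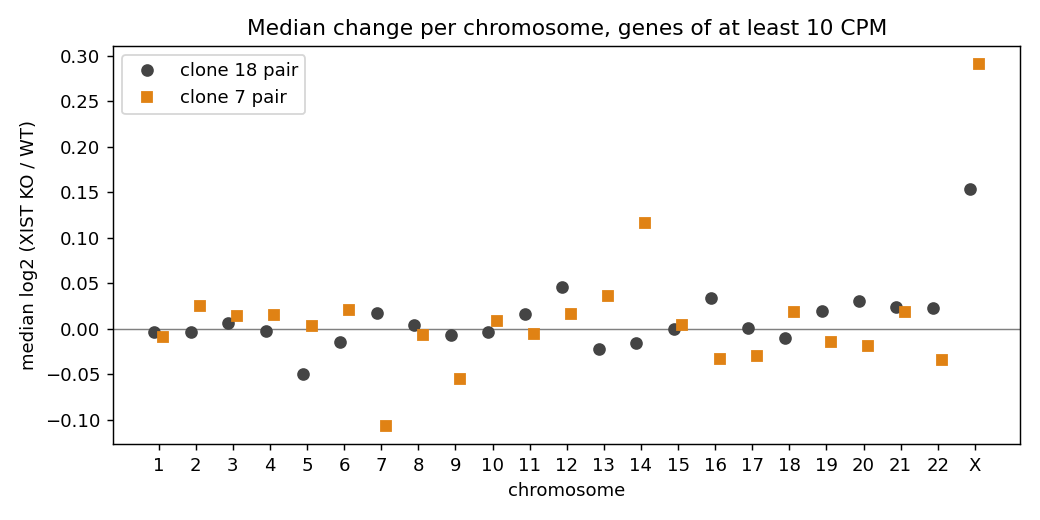
Median log2 ratio of XIST KO to WT (vertical axis) for the genes of each chromosome (horizontal axis) with a mean of at least 10 CPM. Circles are the clone 18 pair and squares the clone 7 pair; X stands at 0.15 and 0.29, and the autosomes lie between -0.11 and 0.12.

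The next 8 X-linked genes were chosen after their values were seen, and none of them passed the adjusted threshold in edgeR. GPC3, a glypican of the cell surface, had a log2 change of 0.94 ± 0.14 and stood at 7.24 CPM in WT clone 7 and 16.3 CPM in its knockout. MSN (moesin, which links actin to the membrane) was at 0.76 ± 0.13, MAGED2 at 0.77 ± 0.16, NGFRAP1 at 1.01 ± 0.23 and BEX1 at 1.35 ± 0.34. SLC7A3, a carrier of cationic amino acids, was at 1.20 ± 0.23, SH3BGRL at 1.38 ± 0.28 and GSPT2, a translation termination factor, at 0.61 ± 0.11. Their adjusted p in edgeR lay between 0.348 for GPC3 and 0.711 for BEX1, and DESeq2 called all but GSPT2. With 1 library or pair left out, GPC3 ranged from 0.13 to 1.89, MAGED2 from 0.36 to 1.19, NGFRAP1 from 0.50 to 1.53, BEX1 from 0.60 to 2.20, SLC7A3 from 0.66 to 1.80 and SH3BGRL from 0.67 to 2.16.

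Genes known to escape X inactivation showed little of this difference. The 28 escape genes had a median log2 change of 0.02 in clone 18 and 0.08 in clone 7, where other X-linked genes of like expression had 0.17 and 0.32. These medians lay at percentiles 0.01 and 0.34 of 10000 matched lists of other X-linked genes, a comparison chosen after the data were seen. Over both pairs 16 of the 28 were higher and 12 lower (median 0.02; camera adjusted p = 0.421), and 0 passed over all genes or adjusted over the list alone. RBBP7, a histone chaperone, was at 0.43 ± 0.14, CTPS2 at 0.43 ± 0.16, AP1S2 at 0.30 ± 0.13 and STS (steroid sulfatase) at -0.94 ± 0.39. STS depended on the trophoblast-like cells described further on, and stood at 0.08 without them. Among the genes of the pseudoautosomal region PAR1, which recombine with the Y chromosome, 6 of 11 tested were higher (median 0.02, mean -0.07; camera adjusted p = 0.987). CD99, a surface glycoprotein, was lower in both pairs at -1.85 ± 0.21 and passed in edgeR adjusted over the list alone (adjusted p = 0.000639) but not over all genes (adjusted p = 0.163, 0.0277 with no filter on low counts, and 1.35e-06 in DESeq2). ASMTL was at 0.86 ± 0.25, SLC25A6, a mitochondrial ADP/ATP carrier, at 0.10 ± 0.13 and ZBED1 at 0.09 ± 0.12.

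Neighbours of XIST in the X inactivation centre were mostly higher in the knockouts. Of 9 tested members 7 were higher (median 0.40; camera adjusted p = 0.0733). The pair medians were 0.34 in clone 18 and 0.69 in clone 7. Of the 9 members 8 are in the X-linked set, which leaves out TSIX though it lies on X. Of all genes in that set 79.3% and 81.5% were higher in clones 18 and 7 (median 0.30 over both pairs). The share of higher neighbours was thus near that of X-linked genes as a whole, and no test against other X-linked genes was made. The list was called with no replicate block (adjusted p = 0.0123), with no filter on low counts (0.0254), with a mean of at least 10 CPM (0.0130) and with equal cells and UMIs per cell (0.00778). All 4 calls were lost with an estimated correlation (adjusted p = 0.791 with no replicate block). In the planned edgeR fit 5 passed adjusted over the list alone and 0 over all genes, where DESeq2 called TSIX (adjusted p = 0.00561). NAP1L2, a nucleosome assembly protein, was at 1.25 ± 0.39 and CHIC1 at 0.79 ± 0.25. TSIX, the antisense partner of XIST, was at -3.32 ± 0.48. It overlaps XIST (73792205 to 73829231, plus strand), so its value is uncertain where reads of XIST could be counted to it.

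The share of all UMIs that came from X-linked genes was larger in both knockouts, with XIST left out. It was 4.09% in WT clone 18 (Wilson binomial interval 4.09 to 4.09) and 4.37% in its knockout (4.36 to 4.37), and 4.10% in WT clone 7 (4.10 to 4.11) and 4.56% in its knockout (4.56 to 4.57). The WT mean was 4.10% ± 0.0101 (SD, n = 2) and the knockout mean 4.47% ± 0.139 (SD, n = 2), a difference of 0.369 percentage points. The pairs differed by 0.278 and 0.460 points, each more than the SD of either group. An exact permutation test gave a two-sided p of 0.33, the smallest it allows with 2 against 2. As an alternative, X-linked UMIs were divided by those of autosomal genes without ribosomal protein genes and the 50 most abundant genes. This ratio had a mean of 7.20% in WT and 7.85% in the knockouts. The difference of 0.647 points thus stands on a higher base and is not a larger effect for that reason.

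**Figure D2:**
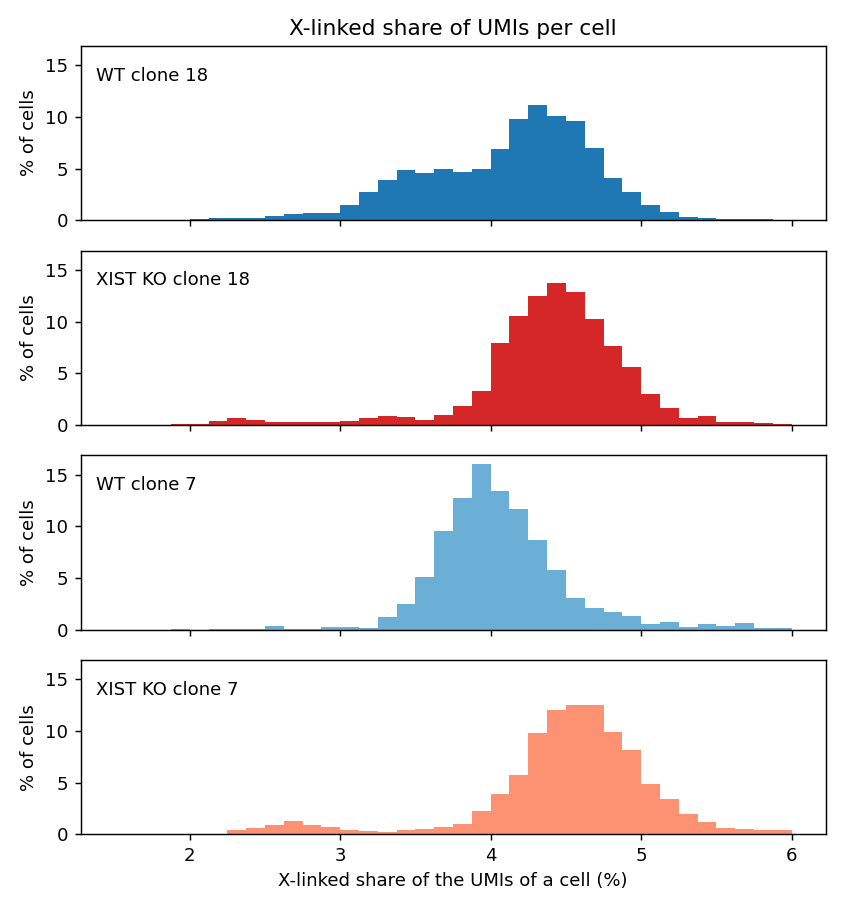
Distribution of the X-linked share of UMIs per cell (horizontal axis, percent) in the 4 libraries, as percent of cells (vertical axis). Library medians were 4.22 (WT clone 18), 4.44 (XIST KO clone 18), 4.02 (WT clone 7) and 4.58 (XIST KO clone 7), and WT clone 18 has a broad shoulder at lower shares.

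Within the WT libraries, cells with at least 1 XIST UMI had a lower X-linked share than cells with none. Cells with none may still hold XIST RNA that was not sampled. After thinning to 15739 UMIs per cell, the mean share in WT clone 18 was 3.70% in 1051 cells with XIST and 4.36% in 1741 cells without, a difference of -0.662 points. In WT clone 7 it was 4.03% in 1272 cells with XIST and 4.19% in 488 without, a difference of -0.153 points. The mean over the 2 libraries was -0.407 ± 0.360 (SD, n = 2), so the libraries differed in size but not in direction, and cells were not used as replicates. With 4 or more XIST UMIs the share was 3.61% in WT clone 18 and 3.93% in WT clone 7. Knockout cells thinned alike had mean shares of 4.39% (clone 18) and 4.58% (clone 7), and XIST was seen in 0.124% of them in clone 18 and in 0 of 1327 in clone 7. Cells too shallow to thin numbered 33 in WT clone 18, 108 in its knockout, 473 in WT clone 7 and 2214 in its knockout.

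**Figure D3:**
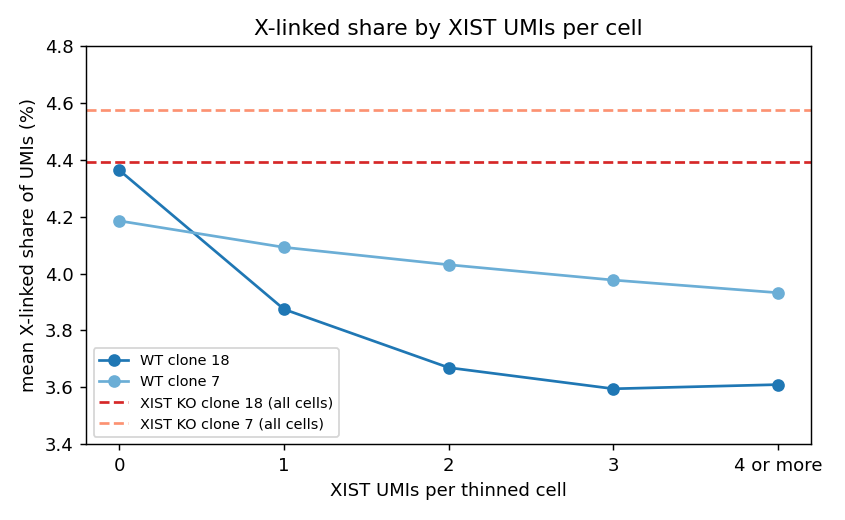
Mean X-linked share of UMIs (vertical axis, percent) of thinned WT cells by the number of XIST UMIs in the cell (horizontal axis). Lines with points are the WT libraries, which go from 4.36 to 3.61 in clone 18 and from 4.19 to 3.93 in clone 7, and dashed lines are the means of all thinned knockout cells, 4.39 and 4.58.

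XIST was the only 1 of 16996 tested genes past the adjusted threshold in edgeR, lower in the knockouts. With no replicate block edgeR called 0 genes, and 104 had an unadjusted p under 0.05. The adjusted p of XIST there was 0.0708. In the blocked fit 946 genes had an unadjusted p under 0.05, of which 501 were higher in the knockouts. Of these 946 genes 164 were X-linked, 159 of them higher. DESeq2's Wald test called 40 genes, 16 higher and 24 lower. Of these 12 were in the X-linked set (11 higher) and 24 autosomal (19 lower). XIST, TSIX and CD99, which lie on X outside that set, were also called, all lower. Leaving out WT clone 7 gave 13 calls in edgeR and leaving out WT clone 18 gave 2.

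Several autosomal genes had far lower values in both knockouts. The 5 named here were chosen after their values were seen, and none passed in the planned edgeR fit (adjusted p from 0.0804 for HSD3B1 to 0.553 for PTN). With no filter on low counts edgeR called HSD3B1 (adjusted p = 0.00513), CCKBR and LINC00643 (both 0.00961). HSD3B1, an enzyme of progesterone synthesis, had a log2 change of -6.99 ± 0.58 in edgeR (adjusted p = 0.0804) and stood at 5.66 CPM in WT clone 18 and 0.0306 CPM in its knockout. LINC00643 was at -5.43 ± 0.51, with 0 counts in XIST KO clone 7, so that its fitted value is no bound. The growth factor gene PTN was at -3.57 ± 0.64, CCKBR, a gastrin receptor, at -3.02 ± 0.30, and NPPB, a natriuretic peptide, at -2.64 ± 0.42. In WT clone 18 PTN stood at 20.6 CPM and CCKBR at 14.3 CPM. Both PTN and CCKBR were among the 10 leading genes of the trophoblast-like cluster, most of whose cells were in that library. DESeq2 called HSD3B1, CCKBR, LINC00643 and NPPB. Without the cells of highest UMI count, an alternative chosen after seeing the data, edgeR called HSD3B1, CCKBR and LINC00643, and without WT clone 7 it called HSD3B1, CCKBR and PTN. Without the trophoblast-like cluster, also chosen after, it called none of the 5: CCKBR was at -0.58, PTN at -1.05 and NPPB at -1.24, and HSD3B1 and LINC00643 were not tested. With 1 library or pair left out, HSD3B1 ranged from -7.70 to -3.33, LINC00643 from -10.36 to -3.79, PTN from -4.91 to -2.01, CCKBR from -3.87 to -1.79 and NPPB from -3.57 to -1.28.

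Trophoblast genes, which mark the lineage that forms the placenta, were lower in the knockouts. Of 17 tested members 16 were lower, with a median log2 change of -0.94, and the pairs differed in size (-1.83 in clone 18 and -0.16 in clone 7). Camera gave an adjusted p of 1.21e-06, which was lost with an estimated correlation (adjusted p = 0.831), and fry made no call. In the planned edgeR fit 0 members passed over all genes, and adjusted over the list alone 6 did, all lower. Over all genes DESeq2 called KRT8 (adjusted p = 0.0103) and VGLL1 (0.0388), and edgeR called GATA3 and XAGE2 without WT clone 7. The 6 included GATA3, a trophoblast transcription factor (-1.79 ± 0.40, from 22.7 to 3.60 CPM in clone 18), and the keratin KRT8 (-0.88 ± 0.19). XAGE2 (-2.34 ± 0.63) and XAGE3 (-2.07 ± 0.45) also passed over the list alone. KRT8 and the XAGE genes have near-identical copies and are uncertain. Trophoblast-like cells made up 2.83% of WT clone 18, 0.269% of WT clone 7, 0.118% of XIST KO clone 18 and 0.169% of XIST KO clone 7. Without the trophoblast-like cluster, an alternative chosen after seeing the data, the list median was -0.31.

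Cancer-testis genes on X, germline genes that some tumours express, were higher in all 4 tested members (median 0.90; camera adjusted p = 0.00013, and 0.831 with an estimated correlation). All 4 are X-linked, and X-linked genes as a whole had a median of 0.30. Camera set the list against all tested genes, so its call includes that wider difference. No test against other X-linked genes was made. In the planned edgeR fit 0 passed over all genes and 3 did adjusted over the list alone, and DESeq2 called VCX3A (adjusted p = 0.00536) and VCX (0.00649) over all genes. VCX3A was at 1.19 ± 0.17, VCX at 1.69 ± 0.38, MAGEB2 at 0.50 ± 0.13 and PAGE4 at 0.60 ± 0.50. VCX3A and VCX are near-identical copies and are uncertain. With no filter on low counts camera's adjusted p was 0.0520, and the call was also lost without WT clone 7 (0.136) and without XIST KO clone 18 (0.450), where the median turned to -0.13. Eight-cell-like genes, active at genome activation in the embryo, were higher in 11 of 12 members (median 0.31; camera adjusted p = 0.00706, 0.133 with no replicate block, and p = 0.831 with an estimated correlation). None passed over all genes or adjusted over the list alone, and all 4 named members lay under 1 CPM in every library. LEUTX was at 1.72 ± 0.65, DUXA at 1.11 ± 0.50, ZSCAN4 at 0.71 ± 0.33 and MBD3L3, which has near-identical copies, at 0.73 ± 0.48. With 1 library or pair left out, LEUTX ranged from 0.21 to 4.17. The call was lost without the trophoblast-like and CCNA1-led clusters, an alternative chosen after seeing the data (adjusted p = 0.382), and with a mean of at least 10 CPM (0.619). It was lost too with equal cells and UMIs per cell (0.553), where the median was -0.08, without WT clone 18 (0.375) and without XIST KO clone 7 (0.182), where it was -0.42.

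In the planned fit camera called none of the 3 pluripotency lists. With a mean of at least 10 CPM it called the naive (median 0.08) and the core list (median 0.14), each with an adjusted p of 0.0225, and both calls were lost with an estimated correlation. For the naive list 17 of 24 members were higher (median 0.08; camera adjusted p = 0.206). GDF3 was at 0.68 ± 0.15, SUSD2, a surface marker of naive cells, at 0.49 ± 0.21, ARGFX at 0.40 ± 0.21 and ALPP, a placental alkaline phosphatase with near-identical copies, at -0.51 ± 0.19. Of 10 core factors 9 were higher (median 0.14; camera adjusted p = 0.141). NANOG was at 0.38 ± 0.11, TDGF1 at 0.41 ± 0.12, DPPA4 at 0.21 ± 0.12 and LIN28A at -0.39 ± 0.12. With 1 library or pair left out, GDF3 ranged from 0.14 to 1.30, NANOG from 0.19 to 0.59 and TDGF1 from 0.0582 to 0.81. Primed genes, which mark the later postimplantation state, were lower in 8 of 12 members (median -0.26; camera adjusted p = 0.0733). In the planned fit fry called the primed list alone among the 21 (adjusted p = 0.0201). That call was lost with no replicate block (adjusted p = 0.992) and without the trophoblast-like cluster (0.116), and fry called 0 lists with DESeq2's size factors, other count filters or stricter cells, and 2 with equal cells and UMIs per cell. ZIC2 was at -1.27 ± 0.42, OTX2 at -0.59 ± 0.28, CD24 at 1.18 ± 0.56 and LIN28B at 0.51 ± 0.25, so its members went both ways. In these 3 lists 0 members passed over all genes or adjusted over the list alone.

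Markers of other cell types gave no call in the planned fit. Without WT clone 7 the primitive endoderm (adjusted p = 0.0488) and fibroblast lists (0.00177) were called, with medians of -0.20 and -0.74, and without XIST KO clone 7 the fibroblast list was (median -1.43; 0.0211). These calls were lost with an estimated correlation, and without WT clone 18 the primitive endoderm median was 0.31. Primitive endoderm genes were higher in 7 of 11 (median 0.15, mean -0.02; camera adjusted p = 0.946). The apolipoprotein APOA2 was at -1.14 ± 0.44, GATA6 at -0.29 ± 0.24, FLRT3 at 0.33 ± 0.32 and HNF4A at 0.23 ± 0.23. Germ layer and amnion genes were higher in 3 of 6 (median 0.01; camera adjusted p = 0.831), with NES at -0.46 ± 0.18, MESP1 at 0.78 ± 0.38, ISL1 at 0.42 ± 0.26 and GABRP at -0.37 ± 0.54. Fibroblast genes were lower in 3 of 5 (median -0.42; camera adjusted p = 0.421). The collagens COL1A1 (-1.15 ± 0.56) and COL1A2 (-1.47 ± 0.68) had changes of -2.38 and -2.77 in the clone 18 pair and 0.13 and 0.17 in the clone 7 pair. FN1 (fibronectin) was at 0.22 ± 0.20 and FBN1 at -0.42 ± 0.41. In these 3 lists 0 members passed over all genes or adjusted over the list alone.

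Proteins that work with XIST were not called either: 13 of 22 were lower (median -0.05; camera adjusted p = 0.664). WTAP, of the RNA methylation complex, was at -0.61 ± 0.23, CIZ1 at -0.36 ± 0.17, the Polycomb methyltransferase EZH2 at -0.30 ± 0.17 and the lamin B receptor LBR at 0.20 ± 0.11. DNA methylation genes were lower in 6 of 9 (median -0.14; camera adjusted p = 0.392). TDG was at -0.27 ± 0.12, TET2 at -0.35 ± 0.21, DNMT3A at 0.19 ± 0.14 and DNMT1 at -0.16 ± 0.11. Imprinted genes were higher in 10 of 19 (median 0.0094; camera adjusted p = 0.831). DLK1 was at 0.76 ± 0.24, PLAGL1 at -1.23 ± 0.42, MEG8 at 0.48 ± 0.30 and KCNQ1OT1 at -0.17 ± 0.11. In these 3 lists 0 members passed over all genes or adjusted over the list alone.

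Stress, signalling and cell cycle genes gave no call in the planned fit. p53 targets were higher in 9 of 15 (median 0.04; camera adjusted p = 0.831), with BTG2 at -0.73 ± 0.18, SESN1 at 0.50 ± 0.24, FDXR at 0.22 ± 0.11 and PHLDA3 at 0.19 ± 0.11. Immediate early and dissociation genes were lower in 10 of 14 (median -0.26; camera adjusted p = 0.114). This list was called with equal cells and UMIs per cell (adjusted p = 0.0381), without WT clone 7 (0.000657) and without XIST KO clone 18 (0.0195). These calls were lost with an estimated correlation, and the median turned to 0.44 without WT clone 18 and to 0.06 without XIST KO clone 7. HSPA1A, which has a near-identical copy, was at -0.32 ± 0.12, IER3 at -0.55 ± 0.21, JUN at -0.26 ± 0.11 and ATF3 at -0.26 ± 0.12. Glycolysis and hypoxia genes were lower in 12 of 21 (median -0.03; camera adjusted p = 0.579). The glucose carrier SLC2A3 was at -0.54 ± 0.18, PGM1 at -0.61 ± 0.21, ALDOC at 0.26 ± 0.13 and NDRG1 at -0.43 ± 0.23. Feedback genes of the ERK pathway were higher in 7 of 12 (median 0.08; camera adjusted p = 0.421), with SPRY2 at 0.58 ± 0.21, DUSP9 at 0.40 ± 0.17, PHLDA1 at 0.33 ± 0.18 and IER3 shared with the list above. S phase genes were lower in 11 of 20 (median -0.0085; camera adjusted p = 0.579). E2F8 was at -0.33 ± 0.23, SLBP at -0.20 ± 0.17, RRM2 at -0.14 ± 0.13 and PCNA at -0.14 ± 0.14. G2 and M phase genes were higher in 14 of 20 (median 0.05; camera adjusted p = 0.579), with CENPE at -0.22 ± 0.11, CENPF at 0.15 ± 0.11, AURKA at 0.15 ± 0.12 and TOP2A at 0.12 ± 0.12. The S phase list was called without WT clone 18 (median -0.24; adjusted p = 0.0341) and, in the other direction, without WT clone 7 (median 0.28; 0.0294). The G2 and M phase list was called without WT clone 7 (median 0.41; 0.00144) and without XIST KO clone 18 (median 0.33; 0.0143), while its median was -0.24 without WT clone 18 and -0.30 without XIST KO clone 7. All calls of these cell cycle lists were lost with an estimated correlation. In these 6 lists 0 members passed over all genes or adjusted over the list alone.

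At the planned Leiden resolution of 0.5, trophoblast-like cells were the only class that could be named from markers, led by CGA, GATA3 and GATA2. Naive cells could not be named by this rule, because their markers were high in most clusters alike. Trophoblast-like cells were 80 of 2825 cells in WT clone 18 (2.83%, exact binomial interval 2.25 to 3.51) and 3 of 2533 in its knockout (0.118%, 0.0244 to 0.346). In clone 7 they were 6 of 2233 WT cells (0.269%, 0.0987 to 0.584) and 6 of 3541 knockout cells (0.169%, 0.0622 to 0.368), within counting error of each other. The mean difference was -1.41 percentage points, and without WT clone 18 it was -0.125. At resolution 0.2 the clone 7 pair turned direction, with 0.358% of WT and 0.537% of knockout cells, so that the lower share rested on clone 18 (3.19% and 0.395%). In WT clone 18 the trophoblast-like cells held 131 CPM of XIST and an X-linked share of 3.11%, against 64.2 CPM and 4.10% in cells outside this and the CCNA1-led cluster. In pooled CPM XIST went the other way in WT clone 7, with 49.0 CPM in its 6 trophoblast-like cells and 97.6 CPM in cells outside both clusters. By detection it did not: XIST was seen in 100% of these 6 cells, which were deeper, and in 81.7% of those outside. In WT clone 18 it was seen in 73.8% and 46.6%. The X-linked shares in WT clone 7 were 3.30% and 4.11%. The CCNA1-led cluster of 373 cells, in which eight-cell-like markers and collagens were both present, stayed unnamed. Naive markers were present in this cluster too, with KHDC1L at 2577 CPM and ALPPL2 at 2995 CPM. It held 4.92% and 4.30% of the WT and knockout cells of clone 18, and 1.84% and 2.37% in clone 7. At resolution 1.0 a cluster of 289 cells with COL1A1, COL1A2 and DCN was named fibroblast-like. It held 4.35% and 3.36% of WT and knockout cells in clone 18, and 1.07% and 1.61% in clone 7. In the clone 18 pair COL1A1 and COL1A2 changed by a log2 of -2.38 and -2.77, far more than this share. The name may thus not hold for all cells of the cluster. A cluster of 81 cells was named eight-cell-like at resolution 1.0 and held 0.496% and 0.908% in clone 18, and 0.717% and 0.791% in clone 7. With 2 libraries against 2, no exact permutation test of a share could go below a p of 0.33.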

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

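The genes in this part were looked at only after the data were seen, outside the planned tests. Of the genes in only 1 of the deposited tables, 2094 had at least 1 UMI, 25 differed within their pair beyond counting error, and 2 of those were higher in the knockout; all 3 counts describe 1 pair of libraries each and carry no replicate. KRT16, a keratin, had 21 UMIs in WT clone 18 and 44 in its knockout. The knockout level was 3.041 times the WT level (95% counting interval 1.77 to 5.38), and KRT16 has near-identical copies, so it is uncertain. The other gene, listed only under the name of a genomic clone, had 0 UMIs in WT clone 18 and 16 in its knockout. Neither gene was in the clone 7 table, and no explanation was tested for either.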

How the results depend on the processing

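The alternatives without the cells of highest UMI count, without the trophoblast-like or CCNA1-led clusters and without cells of low X-linked share, and 5 or more XIST UMIs against none, were chosen after seeing the data; the others were planned. The X-linked difference stayed above 0 in all 14 alternatives without a left-out library (0.20 to 0.36) and with each library or pair left out (0.19 to 0.43); it passed camera's preset test in each setting where that test was run, and failed with the estimated correlation in the planned fit (p = 0.228). The share difference was 0.351 to 0.414 points except over the other denominator, and 0.270 to 0.467 with 1 library left out. Over the other denominator it was 0.647, on a higher base (means of 7.20% and 7.85%). WT cells with XIST were lower by -0.394 to -0.493, and by -0.662 or -0.153 in a single library. The class difference was -1.31 at resolution 0.2 (where the clone 7 pair turned direction, 0.358% of WT and 0.537% of knockout cells), -1.41 at resolution 1.0, and -2.69 to -0.125 with 1 library left out, where WT clone 18 decided it. The settings of every deposited barcode removed no cell and so test nothing, and the alternative of naive-like clusters alone was not run. Depth limits genes under 1 CPM, eight-cell-like genes among them.

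Genes past the threshold numbered 1 in the planned fit, 0 with no replicate block, 40 with DESeq2's Wald test, 7 with no filter on low counts, 8 without the cells of highest UMI count, and 1 to 13 with 1 library left out. The block changed the call of XIST and of the neighbours and eight-cell-like lists in camera, and of the primed list in fry. Lists called numbered 3 in the planned fit, 1 with fry, 5 with a mean of at least 10 CPM and 3 to 7 with 1 library left out, and 0 with an estimated correlation in each setting where that was run. The cause was not tested.

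Of 1057 comparisons of 103 named genes with an alternative that left out no library, 10 reversed, 31 were newly past the threshold (22 genes with DESeq2's Wald test), and 1 was no longer past it. With equal cells and UMIs per cell the eight-cell-like list median turned to -0.0804, the fibroblast one to 0.23, the primitive endoderm one to -0.0886, ZBED1 to -0.00337, HNF4A to -0.0914 and COL1A2 to 0.89. Without the trophoblast-like cluster STS turned to 0.0837, APOA2 to 0.00633, IER3 to 0.0164 and E2F8 to 0.0236; without the CCNA1-led cluster as well STS was at 0.0863, COL1A2 at 0.49, E2F8 at 0.0179 and the fibroblast list median at 0.0905. The primed list median turned to 0.51 with a mean of at least 10 CPM, and the primitive endoderm one to -0.0512 with no replicate block. Medians of 5 further lists within 0.05 of 0 turned too, the farthest being that of germ layers and amnion, at -0.46 with a mean of at least 10 CPM. The cause was not tested.

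With 1 library or pair left out, the eight-cell-like list median ranged from -0.42 to 1.38 and the cancer-testis one from -0.13 to 1.26. Medians of 17 of the 21 lists changed sign, all but those of the escape, neighbours, primed and trophoblast lists. Of the named genes 52 changed sign. A fit without 1 library has no block, so by construction it sets libraries of different pairs against each other. The lowest and highest log2 changes were ZBED1 -0.0435 to 0.22, SLC25A6 -0.0637 to 0.25, CTPS2 -0.0421 to 1.01, STS -1.77 to 0.00821, WTAP -1.58 to 0.56, EZH2 -0.91 to 0.36, LBR -0.0707 to 0.44, ARGFX -0.24 to 1.21 and OTX2 -1.36 to 0.24. Next came CD24 -0.23 to 2.74, LIN28B -0.038 to 1.07, LIN28A -1.12 to 0.27, DPPA4 -0.0461 to 0.46, DUXA -1.09 to 2.93, ZSCAN4 -0.0194 to 1.38, MBD3L3 -0.39 to 1.66, GATA6 -0.70 to 0.14 and FLRT3 -0.35 to 1.00. Ranges for further genes were MESP1 -0.57 to 1.64, ISL1 -0.00233 to 0.85, GABRP -1.17 to 0.42, COL1A2 -2.77 to 0.17, COL1A1 -2.38 to 0.13, FN1 -0.24 to 0.67, FBN1 -1.22 to 0.43, MEG8 -0.16 to 1.16 and SESN1 -0.31 to 1.43. The list goes on with FDXR -0.0553 to 0.46, PHLDA3 -0.20 to 0.53, HSPA1A -0.69 to 0.00124, JUN -1.02 to 0.49, ATF3 -0.74 to 0.30, ALDOC -0.0494 to 0.59, NDRG1 -1.28 to 0.59, SPRY2 -0.19 to 1.49 and DUSP9 -0.30 to 0.96. Others were E2F8 -0.89 to 0.21, SLBP -0.70 to 0.31, RRM2 -0.68 to 0.51, PCNA -0.43 to 0.15, CENPE -0.45 to 0.0397, CENPF -0.30 to 0.57, AURKA -0.53 to 0.76, TOP2A -0.42 to 0.56 and TDG -0.94 to 0.33. The remaining ranges were TET2 -1.34 to 0.46, DNMT3A -0.00713 to 0.39, DNMT1 -0.56 to 0.28, VCX3A -0.24 to 2.71, VCX -0.13 to 4.20, TAGLN -2.79 to 0.87 and MYL9 -2.86 to 1.102.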

Other observations

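The tests of cell clusters, of the share of X-linked genes, of XIST itself, of both trophoblast explanations, and of counting noise, cluster type and chromosome loss were chosen after the result was seen; those of depth and of a few switched-off X-linked genes were set before. The next 6 autosomal genes were chosen after their values were seen, for changes alike in both pairs, and DESeq2 called all 6 while the planned edgeR fit called none. They stand for no wider set, since across autosomal genes the changes of the pairs were not positively correlated (r = -0.011), and 25.1% were higher and 24.3% lower in both. The contractile and actin-binding genes TAGLN (-0.95 ± 0.13), MYL9 (-0.85 ± 0.14) and PALLD (-1.29 ± 0.15) were lower in the knockouts. TAGLN stood at 29.6 CPM in WT clone 7 and 15.8 CPM in its knockout, and at 4.96 and 2.49 CPM in clone 18. The homeobox gene MEIS2 was at -1.50 ± 0.20 and the RNA-binding protein gene IGF2BP1 at -0.80 ± 0.11, while NRG1, a ligand of ERBB receptors, was higher at 0.98 ± 0.15. The adjusted p of PALLD in edgeR was 0.163 and 0.0418 with no filter on low counts, and TAGLN and MYL9 changed sign in fits that left out a library. In those fits PALLD ranged from -2.26 to -0.32, MEIS2 from -1.84 to -1.17, IGF2BP1 from -1.47 to -0.0969 and NRG1 from 0.69 to 1.28.

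COL3A1 and LUM, matrix genes of fibroblasts and chosen after their values were seen, had 401 and 162 UMIs in WT clone 18 and 0 UMIs in its knockout. They were not in the clone 7 table.

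X-linked genes were higher in both knockouts. With equal cells and UMIs per cell the difference was 0.271, so unequal depth does not account for most of it. It was above 0 in all 8 clusters with enough cells, the lowest being 0.153, little above 0.5 of the value over all cells, and the clone 18 pair was at -0.01 in 1 cluster, so a part from the mix of cells stays open. A median over genes gives abundant genes no extra weight, so a few of them could not have produced this difference. At least 79.3% of X-linked genes were higher in each pair. Whether a few abundant genes set the difference in the share of UMIs was not tested. WT cells with XIST had a lower X-linked share by at least -0.153 points in both libraries, so loss of silencing by XIST may be the source, a hypothesis that differences between clones, with 2 libraries per genotype, leave open. Thinned WT cells with no XIST UMI stood at 4.36% in clone 18, near the 4.39% of its knockout. In clone 7 they stood at 4.19%, below the 4.58% of its knockout. The gap of the clone 7 pair was thus also present in cells with no XIST UMI. Such cells may still hold XIST RNA. In WT clone 7 XIST was seen in 72.3% of thinned cells and in 81.5% of all cells before thinning. This gap therefore cannot speak for or against XIST as its source.

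Trophoblast genes were lower in the knockouts, mostly in clone 18. Without the trophoblast-like cluster the list median was -0.313 ± 0.0975 (SE of the median over member genes, which are not replicates), against -0.937 with it. A different number of such cells may account for most of it. The removed cluster held 95 cells at resolution 0.5, and the class held 127 at resolution 0.2. Removal may thus be incomplete, and the source of the remainder stays open. In the clone 7 pair the median was -0.159 ± 0.182 (SE over member genes again), which leaves open whether WT clone 18 alone carries the pattern. Whether XIST affects the number of such cells was not tested, as 1 library held most of them.

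Some cells had an X-linked share under 0.7 of their library's median, a limit chosen after the data were seen. Outside the trophoblast-like and CCNA1-led clusters they were 3.22% and 5.42% of XIST KO clones 18 and 7, and 1.65% and 0.595% of their WT libraries, but over all cells the excess in clone 18 depended on the limit: WT and knockout cells numbered 33 and 50 under 0.6, 85 and 79 (3.01% and 3.12%) under 0.7, and 325 and 141 under 0.8, whereas in clone 7 they were 4 and 116, 14 and 193, and 26 and 251. Counting noise gives at most 0.00233 such cells in a library, which argues against it; at least 97.8% of X-linked genes were lower in those of the knockouts, a value that the picking partly sets, but with cells picked on 1 arm 94.0% to 96.7% of genes on the other were lower, which argues against a few switched-off genes. At most 3.11% of them in a knockout lay in these clusters, and the cluster with most held 38.0% and 30.1% of them in clones 18 and 7 (38.6% and 20.4% of all cells), whereas in WT clone 18 49.4% were trophoblast-like, so only these 2 clusters as a source in the knockouts are argued against. Loss of 1 X chromosome may account for them in the knockouts, where the higher arm ratio was 0.672, but picking for a low share partly sets that ratio, and with cells picked on 1 arm the other arm's was 0.668 to 0.760 there, 0.654 and 0.705 in WT clone 18, and 0.802 and 0.791 in WT clone 7, so it stays open. PAR1 genes were not used for the picking. Their summed counts, in which abundant members weigh most, had ratios of 0.584 and 0.553 in XIST KO clones 18 and 7. In the WT libraries of clones 18 and 7 these ratios were 0.705 and 0.630.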
